A study of Tetrahymena thermophila with 12 samples.

How the data were processed

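Cells of wild type and MN173 were starved for 16 h, stimulated with Alcian Blue at 0.05%, diluted into 0.25% proteose peptone, washed and left to recover, per the labels' protocols. Total RNA was taken before stimulation and 60 min after it, labelled with Cy3 and hybridised to 1-colour NimbleGen arrays, 1 sample per array. Samples were put into the 4 groups by the strain and time in their labels, and replicates were numbered as in the sample descriptions. The letters in the sample titles do not run alongside these numbers in every group: wild-type 60 min replicates 1, 2 and 3 carry the letters B, C and D, and MN173 60 min replicate 3 carries D.

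The deposited probe values are scanner intensities without background correction or normalization, extracted with NimbleScan 2.4.27 per the file headers. The file of wild type 0 min replicate 3 has no header lines and was read with the column order of the other 11. Per-feature values deposited by the authors are RMA values on a linear intensity scale, per the submitters' processing notes, with settings not given in the sources used here. A deposited table of the whole series holds the same intensity values (largest difference 0). They served as an alternative only, and correlated with the values used here at 0.988 to 0.989 per array on the log2 scale.

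Probe intensities were corrected with normexp (offset 50), quantile normalised over the gene probes of the 12 arrays, taken to log2 and summarised per feature by median polish, with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 and version 1.17.8 of data.table). A feature counted as above background on an array when its median raw probe exceeded the 95th percentile of the 4308 random probes of that array. Background correction widens the differences of features with a dim group, its offset narrows them again, and quantile normalization assumes a common distribution on every array, so that a global rise or fall of RNA would not be seen. Between 5 and 253 probes per array were saturated at 65535, and were kept.

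One limma model with 4 group means was fitted to the 19293 tested features, with 8 residual and 4.14 prior degrees of freedom, and 5 comparisons were drawn from it: the time change in each strain, the difference between these changes, and MN173 against wild type at each time. Calls are Benjamini-Hochberg adjusted p under 0.05 within a comparison. Folds against a group in which no array was above background are given as bounds. They use the higher of the feature's own signal and the lowest signal above background on each array. A feature that misses the detection rule can have a signal above that lowest one, so the bounds are not strict. Overlaps were set against n1 × n2 / N per direction. The slope of one strain's change on the other's was corrected by subtracting the mean squared standard error from the variance of the change on the horizontal axis, and was computed both ways.

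The features named were to be the largest by rule. Before the data were examined, it was set that without product names at most 2 features each way would be named per comparison, the largest log2 differences among calls whose arrays do not overlap between the groups (adjusted p alone for the difference between changes). This fallback applied, since none of the 26996 genes of the reference table used here (assembly JCVI-TTA1-2.2) lists an array identifier. For the same reason 22 planned gene lists and 14 fixed gene identifiers were not tested, and no coordinates are given. For the strain comparison at 60 min, these 2 each way took the place of 5 each way.

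On simulated arrays with known changes, 50 features per size, the time comparison in MN173 recovered 48% of features changed by 0.5 on the log2 scale, 86% at 1, 96% at 2 and 100% at 4. The difference between the strains' changes recovered 10%, 72%, 94% and 100%. Among the 19293 simulated features, 12 unchanged ones were called in the time comparison and 9 in the difference between changes. All other features were left unchanged, whereas in the data 72.9% and 53.0% of tested features were called in these comparisons. The Benjamini-Hochberg cutoff was therefore stricter in the simulation, and its shares do not carry over to the data. Within the simulation, changes under 2-fold were incompletely called, most of all for the difference between changes.

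Whether replicate numbers pair the arrays was checked from the deviations of same-numbered arrays from their group means. At 0 min these correlated at 0.22, 0.12 and 0.39 for replicates 1, 2 and 3 of wild type and MN173. Every pair was thus above 0.1, the rule used here. The other 3 pairs of groups checked did not meet this rule (groups that differ in both strain and time were not paired). Between the strains at 60 min the values were -0.06, -0.15 and -0.24. Differently numbered arrays were not compared, so the check cannot establish that the numbers pair the arrays. The title letters A, B and C run alongside the numbers at 0 min, so any pairing could not be credited to one rather than the other. A fit with the replicate number as a block was run for every comparison. Of the arrays, 11 share 1 extraction day of the image files and the remaining one has no header, so no batch could be fitted. The extraction ran in the order of the groups, so any drift in it cannot be told apart from the groups, and the hybridisation batch is not given in the sources used here. Alternatives tried were other background correction, normalization, summary and detection settings, the authors' values, blocks, array weights, other moderation and thresholds, fits with only the arrays compared, and leaving out each array.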

Results

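Transcript levels were measured in the ciliate Tetrahymena thermophila before and 60 min after stimulation with Alcian Blue, a cationic dye that triggers release of mucocysts, the dense-core secretory granules docked beneath the cell surface. The wild-type strain was CU428. The other strain, MN173, is described in the sample labels as an exocytosis-defective mutant, and its cells were treated in parallel in the same way. Each of the 4 groups (wild type at 0 min, wild type at 60 min, MN173 at 0 min and MN173 at 60 min) held 3 one-colour arrays, 12 in all. Each array carried 384999 gene probes for 28064 array features, here meaning sets of up to 14 probes under 1 identifier, and 4308 probes of random sequence that served as background. The median gene probe was 1.30 to 2.14 times as bright as the median random probe. Between 54.3% and 69.9% of features were above background on a given array, and 19293 features (68.7%) were above it on all 3 arrays of at least 1 group and were tested. The files pair no array feature with a gene name, so features are given by their identifiers. Arrays of 1 group correlated at 0.981 to 0.994 across features, which are not independent replicates. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which can be technical, and the number of arrays limits the precision.

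In wild-type cells, the comparison of 60 min with 0 min asks how transcript levels moved during recovery from stimulation. Most of the measured transcriptome changed: 6327 features rose and 7739 fell, together 72.9% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found for 3099 features that rose and 3313 that fell. The strongest changes were mainly increases, with 119 features up and 39 down by at least 16-fold, and 32 up and 0 down by at least 64-fold. Counts by fold size depend on the processing: the authors' values gave 240 up and 136 down by at least 16-fold and 71 up and 10 down by at least 64-fold, and without background correction 14 fell at least 16-fold and 19 rose at least 64-fold. The largest increase was that of TETRA00S0018001, from a log2 intensity of 7.23 ± 0.30 (SD, n = 3) to 15.53 ± 0.11 (SD, n = 3), a log2 change of 8.31 (SE 0.25, adjusted p = 7.73e-11). TETRA00S0007075 rose from 7.35 ± 0.15 to 15.42 ± 0.14 (SD, n = 3 each), by 8.07 (SE 0.10, adjusted p = 1.76e-13). Both features were above background on 2 of 3 arrays at 0 min. TETRA00S0007809 fell from 12.80 ± 0.14 to 7.30 ± 0.31 (SD, n = 3 each), a log2 change of -5.50 (SE 0.16, adjusted p = 5.99e-11), and TETRA00S0016474 fell from 12.42 ± 0.20 to 7.13 ± 0.41, a change of -5.29 (SE 0.18, adjusted p = 2.02e-10). At 60 min they were above background on 2 of 3 and 1 of 3 arrays. The 2 times also differed in handling, since the stimulated cells had been pelleted, exposed to dye, diluted into proteose peptone and washed. Changes are relative to the array as a whole: the median change over the tested features was -0.10, and scaling arrays to a common median moved it by 0.11 and gave 6695 features higher and 6279 lower.

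In MN173 cells, the same comparison asks what the treatment does in a strain with defective exocytosis. The response was again broad, with 7339 features that rose and 6727 that fell, also 72.9% of those tested, of which 2975 and 2788 changed at least 2-fold. Scaling arrays to a common median gave 7742 higher and 5970 lower, and kept 83.1% of the calls. At least 16-fold changes were found for 77 features up and 47 down (143 and 137 with the authors' values, and 23 down without background correction). TETRA00S0001093 rose most, from 7.02 ± 0.19 to 14.97 ± 0.12 (SD, n = 3 each). It was not above background on any MN173 array at 0 min, so its increase is given as at least 244-fold (adjusted p = 3.35e-11), computed from the higher of its own signal and the lowest signal above background on each array. TETRA00S0023320 rose from 7.32 ± 0.26 to 15.06 ± 0.12, a log2 change of 7.74 (SE 0.14, adjusted p = 1.95e-12), and was above background on 1 of 3 arrays at 0 min. TETRA00S0006534 fell from 13.74 ± 0.07 to 7.29 ± 0.16, a change of -6.45 (SE 0.27, adjusted p = 1.71e-09), and TETRA00S0007809, which was among the largest decreases in wild type, fell from 13.55 ± 0.12 to 7.40 ± 0.23, a change of -6.15 (SE 0.16, adjusted p = 3.35e-11). At 60 min they were above background on 1 of 3 and 2 of 3 MN173 arrays, so these sizes rest partly on signals near background.

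The responses of the strains overlapped. Of the features called in both, 4073 rose in both strains and 4680 fell in both, against 2407 and 2698 for independent lists of these sizes. Opposite directions were found for 2034 features, against 5150 for independent lists. The time comparisons share no arrays. Across the tested features, which are not independent replicates, the changes correlated with Pearson's r of 0.60 and Spearman's rho of 0.56. Features that rose in both strains had a median log2 change of 1.11 in wild type and 0.99 in MN173, and those that fell in both had medians of -1.03 and -0.96.

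**Figure D1:**
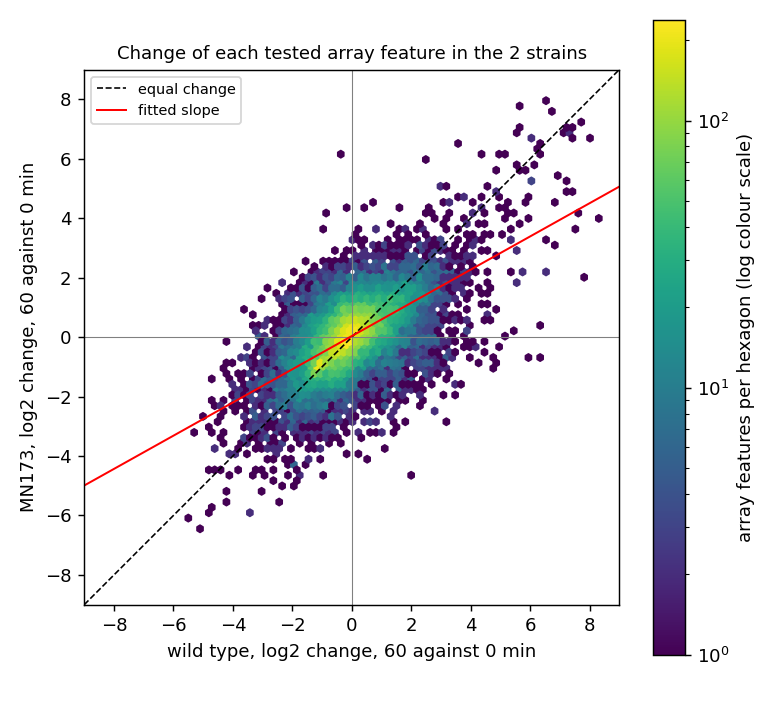
Log2 change from 0 to 60 min in wild type (horizontal axis) and MN173 (vertical axis) for the 19293 tested array features, coloured by the number of features per hexagon on a log scale. The dashed line marks equal change, and the red line has the slope of 0.559 fitted for MN173 on wild type. The cloud is broad around both lines, with r = 0.60 across features.

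The size of the response differed between the strains for 10222 features (53.0% of those tested) by the test of the difference between the strains' changes. The change was higher in MN173 for 5540 features and lower for 4682, and 2648 and 2248 of these differed at least 2-fold. Over the tested features, the noise-corrected SD of the MN173 changes was 0.911 times that in wild type (jackknife SE 0.021). Because the changes were only partly correlated, the noise-corrected slope was below 1 either way: 0.559 (jackknife SE 0.018) for MN173 on wild type and 0.673 (jackknife SE 0.026) for wild type on MN173. Features chosen by a change in one strain are thus no fair basis for comparing response sizes, and the counts that follow are given both ways. Among features that rose in wild type, 2981 had a lower change in MN173, with medians of 1.30 and 0.09, 2690 showed no called difference, and 656 had a higher change in MN173. Among features that fell in wild type, 3373 had a higher (less negative or positive) change in MN173, with medians of -0.97 and 0.10, 3512 showed no called difference, and 854 fell further in MN173. Chosen by MN173 instead, 3340 features that rose there had a higher change than in wild type, with medians of 0.91 in MN173 and -0.15 in wild type, and 1133 had a lower one. Of those that fell in MN173, 2478 had a lower change than in wild type and 901 a higher one. The 119 features that rose at least 16-fold in wild type had medians of 5.18 in wild type and 3.56 in MN173, and the 77 that did so in MN173 had medians of 5.17 in wild type and 4.94 in MN173. Decreases of at least 16-fold in wild type (39 features) had medians of -4.39 in wild type and -3.02 in MN173, and those in MN173 (47 features) had medians of -2.43 in wild type and -4.55 in MN173. Of the features with opposite directions, 805 rose in wild type and fell in MN173, and 1229 fell in wild type and rose in MN173.

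The 2 largest differences each way are given here. TETRA00S0010894 rose in MN173 by 6.07 (SE 0.33, adjusted p = 1.08e-08), while its wild-type change of -0.40 did not pass the test (adjusted p = 0.279), a difference of 6.48 (SE 0.46, adjusted p = 3.72e-07). It was above background on 1 of 3 MN173 arrays at 0 min. TETRA00S0026245 rose by 4.23 in MN173 and changed by -0.85 in wild type, a difference of 5.08 (SE 0.27, adjusted p = 5.32e-08). In the other direction, TETRA00S0019589 rose by 6.37 in wild type and changed by -0.59 in MN173, a difference of -6.96 (SE 0.29, adjusted p = 1.75e-08). TETRA00S0009375 rose by 5.93 in wild type and changed by -0.73 in MN173, a difference of -6.66 (SE 0.24, adjusted p = 1.75e-08). In the order given, these features already differed at 0 min (MN173 minus wild type) by -2.17, -2.03, 1.54 and 1.15, all called. These starting differences are part of the differences between changes. At 60 min the strains differed by 4.30, 3.05, -5.42 and -5.51.

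**Figure D2:**
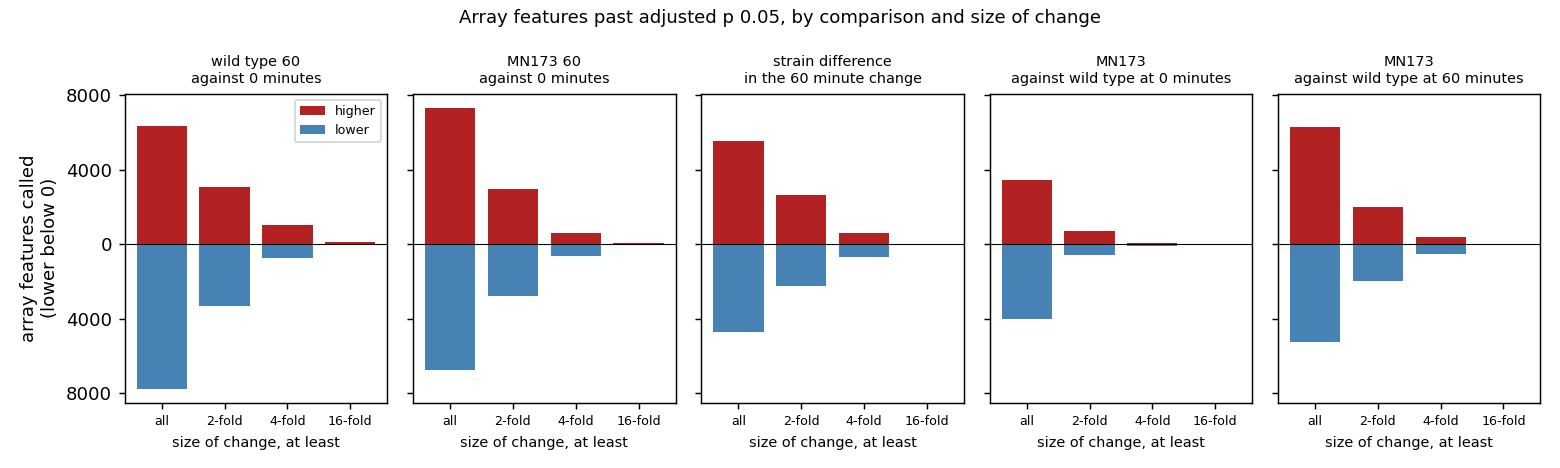
Number of array features past an adjusted p of 0.05 in each of the 5 comparisons, by minimum size of the difference, with higher features above the zero line and lower features below it. The time comparisons call the most features, and the comparison of the strains at 0 min the fewest, 3458 higher and 3989 lower.

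Before stimulation, the comparison of MN173 with wild type asks how the starved strains differed at rest. MN173 had 3458 features higher and 3989 lower (38.6% of those tested). These differences were smaller than the time changes, with 731 features at least 2-fold higher and 577 at least 2-fold lower (1283 and 1327 with the authors' values, and 368 lower without background correction), and 3 each way beyond 16-fold (16 and 15 with the authors' values, and 1 each way without background correction). TETRA00S0020128 stood at 14.97 ± 0.08 in MN173 and 10.28 ± 0.59 in wild type (SD, n = 3 each), a difference of 4.69 (SE 0.22, adjusted p = 4.10e-08). Wild-type cells reached 15.29 ± 0.16 at 60 min, whereas the MN173 change of -0.32 did not pass the test (adjusted p = 0.210). TETRA00S0003274 was at least 20.4-fold higher in MN173 at 0 min (adjusted p = 3.57e-09), since it was not above background on any wild-type array at that time. TETRA00S0004056 was lower in MN173, by a log2 difference of -4.83 (SE 0.15, adjusted p = 2.43e-09). TETRA00S0000646 was at least 25.3-fold lower (adjusted p = 1.71e-07), as no MN173 array at 0 min measured it above background. Both of these bounds equal the measured folds, since the features' own signals exceeded the lowest signal above background. This comparison depended most on the settings: with median scaling 2304 features were higher and 3735 lower.

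**Figure D3:**
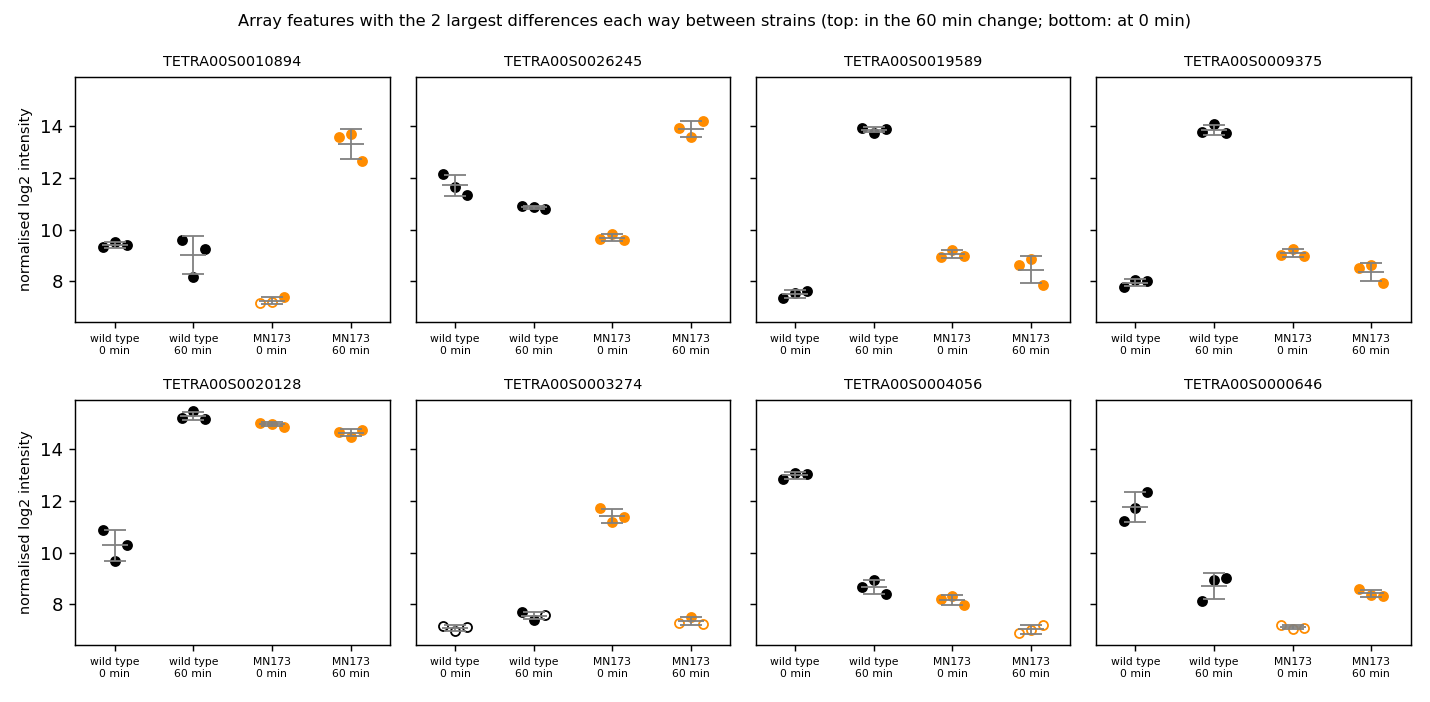
Normalised log2 intensity on each of the 12 arrays for the 2 features each way with the largest strain differences in the 60 min change (top) and at 0 min (bottom). Points are arrays (open where the feature was not above background), black for wild type and orange for MN173, and grey bars are the mean ± SD of 3 arrays. TETRA00S0020128 is near 15 in every group except wild type at 0 min, where its mean is 10.28.

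At 60 min, the strains differed more widely: 6271 features were higher in MN173 and 5216 lower (59.5% of those tested), with 2009 and 1967 at least 2-fold. With median scaling the calls were more even, 5584 higher and 5389 lower. TETRA00S0002432 was higher in MN173 by 5.13 (SE 0.25, adjusted p = 1.30e-08) and TETRA00S0007745 by 4.99 (SE 0.24, adjusted p = 1.18e-08). Before stimulation they were already higher in MN173, by 2.35 (adjusted p = 2.52e-05) and 1.88 (adjusted p = 9.13e-05). TETRA00S0006427 was lower in MN173 by a log2 difference of -5.97 (SE 0.16, adjusted p = 4.71e-10); it was above background on all 3 wild-type arrays at 60 min and on 1 of 3 MN173 arrays. TETRA00S0023887 was lower by a difference of -5.85 (SE 0.19, adjusted p = 1.24e-09). Both had been below background on all arrays at 0 min and rose in wild type by at least 71.9-fold and 226-fold. The strain differences at 0 and at 60 min hardly resembled each other: 2432 features differed in the same direction at both times and 2443 in opposite directions, against 2202 and 2231 for independent lists, and the differences correlated with r = 0.05 across features.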

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

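The pattern weighed here was picked after the results had been seen, and so were the tests of a uniformly weaker response and of compression by background. Because the response in MN173 differed from that in wild type by the test of the difference itself, 10222 features are listed here, among them 2034 called in opposite directions in the strains. The 2 largest each way are TETRA00S0010894 (log2 difference between the changes 6.48), TETRA00S0026245 (5.08), TETRA00S0019589 (-6.96) and TETRA00S0009375 (-6.66).

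A uniformly weaker response in MN173 is argued against as the whole cause. With 0.559 times the wild-type change subtracted from the MN173 change, 56.9% of the tested features were called. With the whole wild-type change subtracted it was 53.0%. The scaled difference has a smaller standard error, so these shares are not comparable, and how much the scaling accounts for was not measured. Other factors were not tried. Single probes that hybridise to something else are argued against too. Of the called features, 99.4% had the same sign in both sets of their probes, first and last along the feature. Calls rest on these same probes, and median polish already limits single ones, so this agreement was partly built in. Over all tested features with more than 1 probe, called or not, the differences from both sets correlated at 0.948. Compression of dim features by background is argued against as the whole cause. Of 8120 features at least 4-fold above the background level in every group, 29.0% were called with a difference of at least 2-fold, and 28.3% to 30.2% with any 1 array left out. A smaller contribution of signal over background stays open, since 52.2% of the 4823 brightest features were called against 53.0% of all. Biological differences between the strains beyond exocytosis are not separable from the mutation here, and were not tested.

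Chance was examined by regrouping arrays. For the difference between the strains' changes, 100 splits of the arrays into times within each strain, the real one included, do not bear on chance. All 82 that moved arrays in both strains called 0, as the large time changes then lie in the spread, and the 16 that moved arrays in 1 strain called 2509 to 7458 features, which holds the other strain's time change. The real split called 10222, and 2 of the 100 called as many: the real one and the one with the times exchanged in 1 strain, which called 15265 and measures the sum of the changes. For the other comparisons, 3 arrays against 3 give 10 splits, too few for a share under 0.05. The real splits called 14066 features for the time change in wild type, 14066 in MN173, 7447 for the strains at 0 min and 11487 at 60 min, and the highest of the other splits called 0 in each case (1 split as large each time, the real one). Those other splits mix the real groups, so the real differences lie in their spread, and their 0 does not bear on chance either.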

How the results depend on the processing

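Directions were kept by each of the 20 named results under every setting run, in 240 values with 1 array left out and 272 under other settings, all past the threshold. They were picked as the largest differences on these same arrays, so this says little about typical calls. Over all called features, median scaling turned the sign of 409 in the MN173 time change (83.1% of calls kept), 90 in the difference between changes (81.1%), and 19, 7 and 5 in the strains at 60 min, at 0 min and in the wild-type change. Leaving out each array moved none of the counts of calls, shared directions and response classes by over 1.5 times, nor those by fold size (except the 0 features at least 64-fold lower in MN173 at 60 min, which became 1 or 2). Among calls the widest range was that of the strain comparison at 0 min, 2720 to 3707 features higher and 2916 to 4312 lower, lowest without wild type 0 min replicate 2, when 75.2% of its calls were kept. Requiring at least 2-fold changes left 3099 higher and 3313 lower in wild type, 2975 and 2788 in MN173, 2648 and 2248 for the difference between changes, 731 and 577 for the strains at 0 min, 2009 and 1967 at 60 min, 3016 shared in direction and 291 opposite. An adjusted p under 0.01 left 2280 higher and 2471 lower at 0 min and 1312 opposite. Stricter thresholds call fewer by construction. At 0 min, median scaling gave 2304 higher and 3735 lower, and array weights gave 5282 higher and 6855 lower. The cause was not tested, and the array weights did not converge (22.6 for wild type 0 min replicate 2), so those counts are unreliable. With the authors' values, at least 2-fold counts rose to 4529 higher in MN173 over time, 4048 higher for the difference between changes and 3306 higher at 60 min. Median scaling gave 484 features that fell further in MN173 (854 in the main run) and 546 that fell in MN173 with a higher change than in wild type (901). The slope of MN173 on wild type ranged from 0.543 to 0.567, and the reverse one from 0.645 to 0.702.

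With the replicate block the strain comparison at 0 min called 3523 higher and 4151 lower, and 3743 and 4668 over the 0 min arrays alone, a fit chosen after seeing the data; it changed no call of a named feature. The title letter as a random block had a correlation of 0.08. As a fixed effect it kept 81.0% of the calls of the difference between changes and 90.3% and 89.4% of the time changes in wild type and MN173, and gave 1635 opposite directions. The 22 gene lists, camera and fry were not run, as no identifier could be matched to a gene. Batch as a block was not run either, as 11 arrays share 1 extraction day and the hybridisation batch is not given. The deposited series table equals the per-feature values and gives no separate result. Signal over background, 1.30 to 2.14, limits dim features.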

Other observations

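The patterns below were picked after the results had been seen. So were the test of a strain difference kept at full size and the check, by shuffling, of the test on features without a time change. Some features went from above background on all 3 arrays of a group to below it on all 3 of another, with a called difference of at least 2-fold. In wild type, 191 features were above background at 60 min alone and 153 at 0 min alone. In MN173, 221 and 107 features did so. These counts rest on detection, and the arrays differed in signal over background, which was 1.65 to 1.91 in wild type at 0 min, 1.30 to 1.78 in wild type at 60 min, 1.36 to 1.47 in MN173 at 0 min and 1.65 to 2.14 in MN173 at 60 min, so the excess at 60 min in MN173 runs with brighter arrays. Single arrays decide much of them. Without wild type 60 min replicate 1 the 153 became 304, and without MN173 0 min replicate 3 the 221 became 358. Without MN173 60 min replicate 2 the 107 became 207. Fewer arrays are then needed, and each array left out here had the most features above background in its group. Between the strains such switches were fewer, 31 in MN173 and 34 in wild type at 0 min, and 46 and 63 at 60 min. The 34 became 90 without MN173 0 min replicate 3, the 46 became 131 without wild type 60 min replicate 1, and the 63 became 100 without MN173 60 min replicate 2.

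Features with consecutive identifiers changed together more than distant ones. Over 14699 pairs, the correlation between neighbours was 0.18 for the wild-type change, 0.21 for the MN173 change and 0.14 for the difference between the changes, each with a permutation p of 1e-04, adjusted over 5 comparisons, the smallest that 10000 permutations can give. At 50 identifiers apart it was 0.01 for the wild-type change. The position of the probes on the array is argued against, since the median distance between probes of neighbours was 0.996 of that of features 50 apart. Similar length or level is argued against for the wild-type change, the only one tested, since removing these trends left 0.9499 of its correlation. Whether some neighbours measure 1 transcript or its close copies cannot be told here: nearly equal profiles were 7.04 times as frequent among neighbours (2.50% against 0.356% of pairs), but mean levels correlated at only 0.09.

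The strain differences at 0 and 60 min hardly resembled each other (r = 0.05). Array noise at 0 min is argued against, since the difference from replicate 1 correlated at 0.825 with that from replicates 2 and 3. The normalization is argued against too, as the highest correlation among other background corrections, normalizations and probe summaries and the authors' values was 0.0549 (0.0576 with array weights). Among the 1948 features called in neither time comparison the correlation was 0.765, above the bound set for a constant difference hidden by the response. The choice of features builds in a high correlation, since a feature unchanged over time in both strains keeps its strain difference. The test is therefore void, and the explanation cannot be told apart by it. With MN173 features shuffled the correlation was 0.995, but this pairs features of unlike level and does not measure how much is built in. A difference kept at full size over all features would need a slope of 1, and the slope was 0.0898 (jackknife SE 0.0236).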
